A study of Rattus norvegicus with 30 samples.

How the data were processed

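RNA of 30 kidneys, 1 from each of 30 Sprague-Dawley rats, was sequenced in 30 libraries. Per the labels' protocols, whole frozen kidneys were powdered in liquid nitrogen, RNA was isolated with TRIzol and a column kit, and poly-A libraries were made with a stranded KAPA kit and read as 75-bp pairs on a HiSeq3000. Groups were taken from the labels, which give the dose and the time of every animal. The sex of the animals is not given in the sources used here.

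Each library has 1 deposited file with 65166 targets: 40071 transcripts with Ensembl transcript IDs and 25095 genomic intervals named by chromosome, start and end, 1003 to 20000 bp long. Per the file headers, each target has a length, an effective length, an estimated count and a TPM value (count scaled to length and library). The deposited estimated counts come from kallisto 0.42.2, per the submitters' processing notes, which also name the genome build Rnor_6.0. kallisto shares a read pair that matches several targets among them, so the deposited estimated counts need not be whole: 21848 transcripts had whole counts in every library, within 1e-06, and 7356 transcripts had none in any library. The deposited TPM values are the estimated counts divided by the effective length and scaled to a common sum, so that they keep no depth. The annotation release and the options of kallisto are not given in the sources used here. How the genomic intervals were chosen is not given either.

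The files do not pair transcripts with genes. The reference table used here lists 47357 genes of another assembly, and 0 of its cells held an Ensembl transcript ID. Counts were therefore not summed per gene, as had been planned, and the tests were made per transcript. The gene list tests (injury markers, stress responses, nephron segments, immune cells, metabolism and others) and the panel of marker genes that had been fixed before the data were examined were not run, since no list could be matched. No more than 2 IDs that rose and 2 that fell are given.

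Library totals were 21.6 to 41.8 M estimated counts. Genomic intervals held 5.82 to 9.23% of them and were left out of the library sizes and of the main tests. The transcripts' totals were 20.2 to 39.1 M. No pair of libraries of 1 group agreed within sampling noise. The chi-square per degree of freedom over their transcripts was 14.99 at the lowest, where sampling noise alone gives 1.

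Estimated counts were rounded to whole numbers. Transcripts were kept by the filterByExpr function of edgeR 4.0.16 over all 30 libraries (21112 kept, 8256 of them with whole counts). Each comparison was fitted with edgeR's quasi-likelihood test with robust estimation and TMM normalization, on the libraries of the groups compared. P values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was taken as a call. The SE given with an edgeR log2 fold change is its size divided by the square root of the test's F value. It is derived from the test and is no separate estimate of error. Levels are in counts scaled to the library size (CPM) after TMM normalization, unless said otherwise. The test was tried on simulated counts with the means, library sizes and spread of the real libraries. In each set, 200 transcripts of at least 5 CPM were changed, and all transcripts varied independently of one another. For the 7 comparisons of 5 with 5 libraries, the test recovered 77 to 94% of 2-fold changes and 96 to 100% of 4-fold changes, with 4 to 10 false calls. Fewer changes, lower levels and single outlying libraries were not simulated, so these shares need not hold for them.

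Fixed before the data were examined were 9 comparisons: each dose with the vehicle and the high with the low dose at each time, the change of each dose's effect from 10 to 34 h, and vehicle at 34 h with vehicle at 10 h. Added later were 2 comparisons, each dose with the vehicle over both times. Alternatives fixed beforehand were the size factors of DESeq2, DESeq2 1.42.0 itself, limma 3.58.1 voom with quality weights, no filter on low counts, a filter of 5 CPM in 5 libraries, a single fit of all 30 libraries, limma on log2(TPM + 1), offsets for the effective length, the run of library numbers at 34 h as a covariate for the high dose comparisons, and each library left out in turn. DESeq2 gives no adjusted p to transcripts that its own filters set aside, 165 to 11059 per comparison. Alternatives added later were transcripts with whole counts only, the calls of DESeq2 in the overlaps, the same covariate for low dose against vehicle at 34 h, and the fit without 4 libraries that stand apart. The calculations were made in R 4.3.3 and Python 3.11.15 with scipy 1.17.1.

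Transcripts to be named were chosen by a rule fixed beforehand: called, with a mean of at least 5 CPM over the libraries compared and, for comparisons with vehicle, all treated libraries on 1 side of all vehicle libraries, in order of the size of the change. The rule also asked for a gene symbol, which no transcript here has. ENSRNOT00000072819, with a mean of 4 CPM, lies outside the rule and was named after its values were seen.

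Whole profiles were compared on log2(CPM + 1), without TMM, over 12929 transcripts with a mean of at least 5 CPM. The share of variance between 2 groups was tested by all 126 splits of 10 libraries (an exact permutation test), which allows no p below 0.0079. Any split holds some share, so a share alone shows no effect: 9.2% between high and low dose at 34 h was reached by 113 splits. For each library, the distance to its group was the root mean square difference in log2 units from the mean of the other 4 libraries. Tests between groups permuted these distances as fixed values. The distances of 1 group depend on each other, so their permutation p is a rough guide only. A library was said to stand apart if at least 100 transcripts, of at least 1 CPM, were over 2-fold above or under all 29 other libraries. On simulated libraries in which 200 transcripts of 1 library were raised 8-fold, 100% of them were found, and no other library had over 4 such transcripts. These profile measures were chosen after the data had been seen.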

Results

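Gene expression was measured by RNA sequencing in whole kidneys of 30 Sprague-Dawley rats, an outbred stock, after a dose of mercury chloride (HgCl2), a salt that is toxic to the kidney's tubules, or of saline. The animals formed 6 groups of 5. The vehicle groups received saline at 1 ml/kg, the low dose groups 0.25 mg/kg HgCl2 and the high dose groups 0.50 mg/kg HgCl2, and kidneys were taken at 10 or 34 h. The doses were meant to give injuries of different degree. Each kidney was powdered whole, so that a library averages over all its parts and cell types.

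Depth overlapped between all groups. Estimated counts on transcripts were 29.2 ± 1.98 M (M, mega; SD, n = 5) in vehicle, 31.8 ± 4.71 M in low dose and 31.0 ± 3.05 M in high dose libraries at 10 h. At 34 h they were 28.5 ± 3.24, 29.1 ± 7.16 and 31.1 ± 2.31 M. The reads carry no molecular identifiers, so counting error alone understates the error. At 10 h each dose group is 1 unbroken run of library numbers (31 to 35 low dose, 36 to 40 vehicle, 56 to 60 high dose). Dose and any batch that follows these numbers cannot be told apart at that time. At 34 h the low dose is also 1 unbroken run (46 to 50), with vehicle libraries before it (43 to 45) and after it (51 and 52), and the high dose is 41, 42 and 53 to 55. A batch made up of the low dose libraries alone cannot be told apart from that dose.

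Several single kidneys stood far from all others. In 4 of the 30 libraries, at least 100 transcripts lay over 2-fold beyond all 29 other libraries. These were high dose replicate 2 at 10 h (141 transcripts higher, 29 lower), high dose replicate 3 at 34 h (305 higher, 87 lower), high dose replicate 4 at 34 h (64 higher, 513 lower) and vehicle replicate 2 at 10 h (295 higher, 1 lower). In the other libraries no more than 29 were higher and 13 lower. The distance of a library to its group was 0.411 ± 0.115 log2 units (SD, n = 5) in the high dose at 34 h, 0.273 ± 0.029 in the vehicle and 0.260 ± 0.0281 in the low dose at that time. The exact permutation p was 0.0238 for high dose against vehicle and 0.0159 for high against low dose (two-sided, 0.0714 for both after adjustment over 6 comparisons). The distances of a group are not independent of each other, so these p values are a rough guide only. Without the libraries that stand apart, the exact p against vehicle was 0.107 and that of high against low dose 0.0357.

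**Figure D1:**
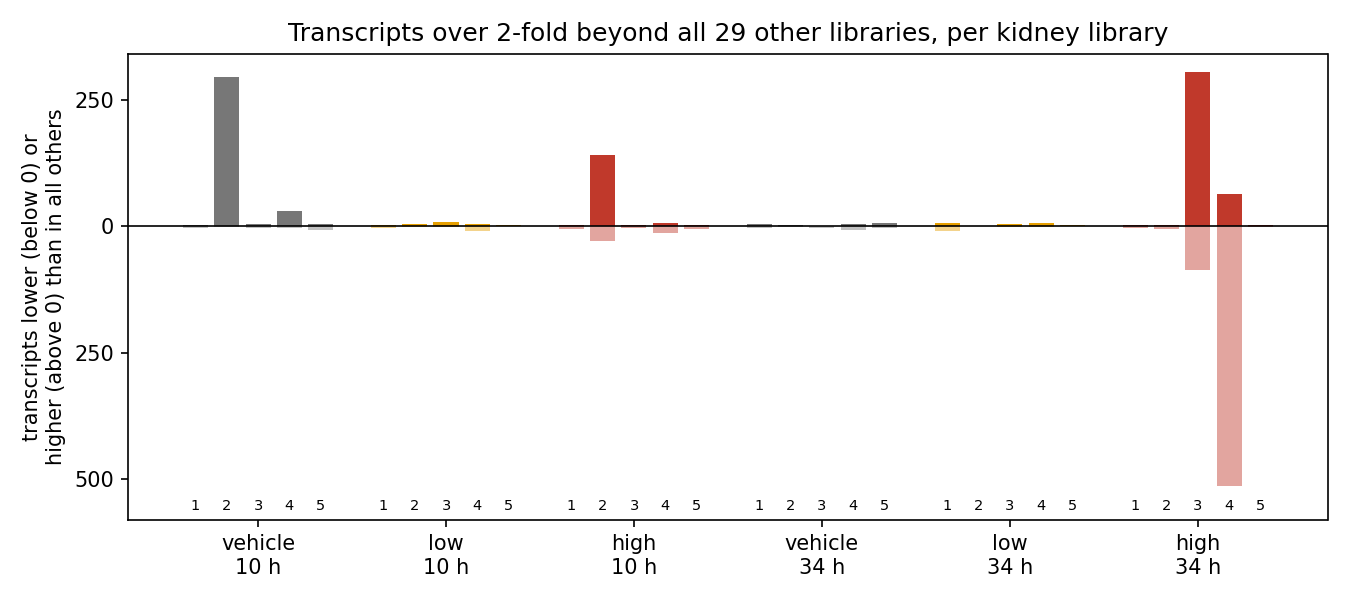
Number of transcripts in each kidney library that were over 2-fold higher (bars above 0) or over 2-fold lower (pale bars below 0) than in all 29 other libraries, by group and replicate (numbers at the bottom; gray vehicle, orange low dose, red high dose). The highest bar is high dose replicate 3 at 34 h with 305 transcripts and the lowest is high dose replicate 4 at 34 h with 513.

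At 10 h after the low dose, no transcript passed the test against the vehicle. edgeR called 0 of 21112 transcripts, where 1904 had an unadjusted p under 0.05, DESeq2 called 76, and limma voom with quality weights and limma on log2(TPM + 1) called 0. Between these groups lay 14.4% of the variance of whole profiles (exact permutation p = 0.127, adjusted 0.222 over 7 comparisons). On simulated data with 200 changed transcripts of at least 5 CPM, the edgeR test recovered 86% of 2-fold changes for this comparison. This share need not hold for fewer changes or lower levels. Leaving out low dose replicate 4 gave 3 calls and leaving out vehicle replicate 3 gave 1.

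At 10 h after the high dose, a single transcript rose. ENSRNOT00000001792 stood at 32.2 ± 1.98 CPM (SD, n = 5) after the high dose and at 20 ± 1.64 CPM in the vehicle, with every high dose library above every vehicle library. Its log2 fold change was 0.69 (SE 0.08, edgeR adjusted p = 0.0473). In the low dose at 10 h the level was 21.8 ± 2.60 CPM, and the high against low dose difference did not pass the test (log2 0.55, edgeR adjusted p = 0.0835). At 34 h it was 20.8 ± 6.07 CPM in the high dose and 24.2 ± 1.39 CPM in the vehicle, a log2 difference of -0.22 (SE 0.18) with an edgeR adjusted p of 0.855. All its estimated counts were whole, which is no proof that its reads matched no other target.

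The edgeR test called no other transcript for the high dose at 10 h, while 2968 had an unadjusted p under 0.05. The count rests on the method: DESeq2 called 975, limma voom with quality weights 11, the fit of all 30 libraries 62, and limma on log2(TPM + 1) 0. The call of ENSRNOT00000001792 was lost with each of the 10 libraries left out in turn, with log2 fold changes of 0.63 to 0.71. Between the high dose and the vehicle, 15.3% of the variance of whole profiles lay between the groups (exact permutation p = 0.0476, adjusted 0.167).

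Between the high and the low dose at 10 h, edgeR called 0 transcripts, with 3633 at an unadjusted p under 0.05. DESeq2 called 1120, limma voom with quality weights 2410, limma on log2(TPM + 1) 4 and the fit of all 30 libraries 674. The edgeR count was 184 without high dose replicate 2, 202 without low dose replicate 4, 1 without low dose replicate 5 and 0 with each of the other 7 libraries left out. Here 19.2% of the variance lay between the groups (exact permutation p = 0.0873, adjusted 0.204).

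At 34 h after the low dose, 6 transcripts rose and 1 fell. ENSRNOT00000051422 rose from 2.87 ± 0.59 CPM in the vehicle to 8.76 ± 2.16 CPM (SD, n = 5), a log2 fold change of 1.61 (SE 0.19, edgeR adjusted p = 0.0311). ENSRNOT00000051259 fell from 14.1 ± 0.77 to 8.73 ± 1.09 CPM, a log2 fold change of -0.70 (SE 0.09, edgeR adjusted p = 0.0446). In all 7, every low dose library lay on 1 side of every vehicle library. Chance gives this in 0.79% of unselected transcripts, but these were selected by the test between the same groups, so the separation adds no evidence. One of the other risers had no counts in any vehicle library of 34 h and 3 ± 0.49 CPM in the low dose.

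The named transcripts also varied within and between groups at 10 h. ENSRNOT00000051422 had 8.50 ± 2.27 CPM (SD, n = 5) in the vehicle at 10 h and ranged from 2.69 to 13.0 CPM within the low dose at 10 h. ENSRNOT00000051259 ranged from 5.87 to 15.4 CPM in that group. At 34 h the high dose lay between vehicle and low dose for both, at 6.89 ± 2.80 and 10.8 ± 1.27 CPM, and neither passed the test against the vehicle (log2 1.26 and -0.39, edgeR adjusted p = 0.822 for both). In the vehicle at 34 h, all 6 transcripts that rose had the lowest mean of the 6 groups, and ENSRNOT00000051259 had its highest. The calls thus rest on these vehicle libraries as much as on the low dose.

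None of the 7 had whole counts, so that each shared reads with other targets, and their levels are uncertain for that reason. The test left 3017 transcripts with an unadjusted p under 0.05. DESeq2 called 443 but gave no adjusted p to 11059 of the 21112 transcripts, among them 5 of the 7, of which ENSRNOT00000051422 is 1. The limma test on log2(TPM + 1) called 6, and limma voom with quality weights 4, without ENSRNOT00000051422 (adjusted p = 0.066). The fit of all 30 libraries called 0, and a test of transcripts with whole counts only, added later, 0. With the run of library numbers as a covariate, also added later, edgeR called 1, and the log2 fold changes of ENSRNOT00000051422 and ENSRNOT00000051259 were 1.57 and -0.70. That fit sets the low dose against the 3 vehicle libraries numbered 43 to 45 alone. Leaving out any of the 10 libraries left 1 to 4 calls. The call of ENSRNOT00000051422 ended in 8 of these 10 fits (all but those without low dose replicate 4 or vehicle replicate 4) and that of ENSRNOT00000051259 in 9 (all but that without low dose replicate 4). Between low dose and vehicle at 34 h, 17.2% of the variance lay between the groups (exact permutation p = 0.0317, adjusted 0.167).

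**Figure D2:**
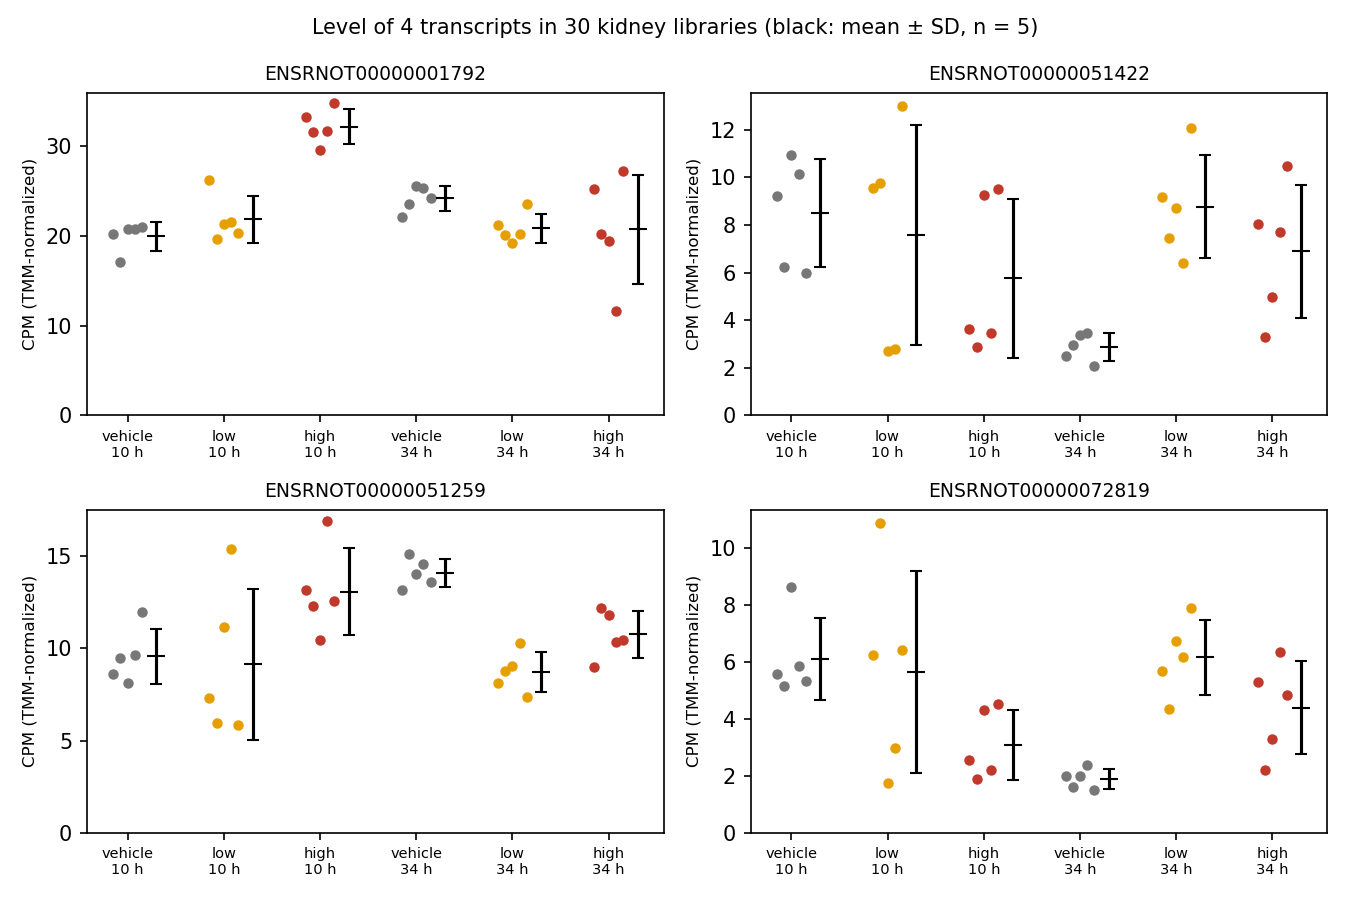
Level of 4 transcripts in CPM (TMM-normalized) in the 30 kidney libraries. Points are libraries (gray vehicle, orange low dose, red high dose) and the black marks beside them are mean and SD (n = 5). ENSRNOT00000001792 stands at 32.2 CPM after the high dose at 10 h, while the other 3 transcripts spread widely within the low dose at 10 h.

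At 34 h after the high dose, edgeR called 0 transcripts, with 1165 at an unadjusted p under 0.05. DESeq2 called 41, limma voom with quality weights and limma on log2(TPM + 1) 0, and transcripts with whole counts alone, tested later, 3. Left out in turn, vehicle replicates 1, 2 and 3 and high dose replicate 5 gave 1 call each. The groups held 12.2% of the variance (exact permutation p = 0.246). On simulated data with 200 changed transcripts of at least 5 CPM, 77% of 2-fold and 97% of 4-fold changes were recovered in this comparison. These shares need not hold for fewer changes or lower levels. High and low dose at 34 h gave 0 calls by edgeR, with 678 transcripts at an unadjusted p under 0.05, 3 calls by DESeq2, 0 by both limma tests and 9.2% of the variance (exact permutation p = 0.897). With the run of library numbers as a covariate, both of these edgeR counts stayed at 0. For high against low dose, that fit sets the high dose libraries numbered 41 and 42 alone against the low dose.

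The effect of the high dose changed from 10 to 34 h in 2 transcripts, tested as the difference of both effects with edgeR. One stood at 15.95 CPM on average in the high dose and 11.4 CPM in the vehicle at 34 h, against 10.4 and 14.7 CPM at 10 h, a log2 difference of 1.00 (SE 0.15, adjusted p = 0.0373). The other was near the detection limit, with a mean of 0.79 CPM, and differed by 5.56 (SE 0.86, adjusted p = 0.0373). Both had whole counts. The test left 2833 transcripts with an unadjusted p under 0.05. DESeq2 called 156, limma voom with quality weights 4, edgeR without the filter on low counts 0 and the fit of all 30 libraries 1. With single libraries left out, edgeR called 0 to 5, and 0 in 13 of 20 fits. For the low dose, edgeR called 0 changes of effect (1344 with an unadjusted p under 0.05), DESeq2 19 and both limma tests 0, and edgeR called 2 without low dose replicate 5 of 10 h.

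Without mercury, 1 transcript fell from 10 to 34 h. ENSRNOT00000072819 fell from 6.11 ± 1.44 to 1.90 ± 0.35 CPM (SD, n = 5) between the vehicle groups, a log2 fold change of -1.69 (SE 0.19, edgeR adjusted p = 0.0395). It is also 1 of the 6 that rose in the low dose at 34 h, to 6.16 ± 1.31 CPM (log2 1.70, SE 0.18, edgeR adjusted p = 0.0152). Both differences rest on the same 5 vehicle libraries of 34 h, which had the lowest mean of the 6 groups. The low and high dose at 10 h were at 5.65 ± 3.55 and 3.1 ± 1.23 CPM, and the high dose at 34 h at 4.39 ± 1.64 CPM. These calls are therefore not independent of each other. DESeq2 called 131 transcripts between the vehicle groups, and limma voom with quality weights and the fit of all 30 libraries called 0. On log2(TPM + 1), limma did not call ENSRNOT00000072819 between these groups (adjusted p = 0.106). Of the 10 libraries left out in turn, 8 ended the call of ENSRNOT00000072819, all but vehicle replicate 3 of 10 h and vehicle replicate 4 of 34 h. Its call for the low dose at 34 h ended in 6 of 10, those without low dose replicates 1 or 3 or vehicle replicates 1, 2, 3 or 5.

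The calls of edgeR could not be shared between the doses, since it called 0 transcripts for the low dose at 10 h and 0 for the high dose at 34 h (1904 and 1165 at an unadjusted p under 0.05, 76 and 41 called by DESeq2, 0 by both limma tests). Of the DESeq2 calls, compared later, 8 were shared in the same direction at 10 h (76 for the low and 975 for the high dose) and 14 at 34 h (443 and 41). In 20 simulations of unchanged groups 0 to 4 were shared at either time, with no more than 39 calls for a dose. With the vehicle libraries divided between the doses, 0 to 2 were shared at 10 h and 1 to 4 at 34 h. The low and high dose comparisons use the same vehicle libraries, which alone makes their fold changes alike. Across transcripts, which are not independent replicates, Pearson's r of the log2 fold changes was 0.615 at 10 h and 0.618 at 34 h. In 20 simulations of unchanged groups it was 0.511 and 0.498 (medians). The covariance was 0.23 and 0.197, against 0.133 in the simulations of both times. The share of transcripts with the same sign went the other way at 10 h: it was 55.7%, under the 65.7 to 67.3% of the simulations, and at 34 h it was 71.6%, above their 66 to 67.1%. All these simulations drew each transcript independently, so their ranges lack the variation that real transcripts share. A value outside them therefore decides nothing on a shared effect of the doses. With the vehicle libraries divided between the doses in 20 ways, the median r was -0.00381 at 10 h and 0.185 at 34 h. The share with the same sign was then 40.2 to 56.1% at 10 h and 54 to 64.6% at 34 h. The high dose calls of edgeR at 10 h and at 34 h (1 and 0 transcripts) could not overlap either, and of those of DESeq2, 2 that rose and 1 that fell were shared (Fisher's exact p = 0.122 and 0.19 across transcripts).

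Taking both times together, a comparison added after the data had been seen, edgeR called 0 transcripts for the high dose (1453 with an unadjusted p under 0.05) and 0 for the low dose (3886). DESeq2 called 50 and 884, limma voom with quality weights 13 and 1311, and limma on log2(TPM + 1) 0 and 0. The low dose count rose to 2075 when low dose replicate 4 of 10 h was left out and to 22 without low dose replicate 5 of 10 h. The high dose count was 4, 2 and 1 without high dose replicates 2, 3 and 5 of 10 h.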

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

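The tests of depth, of a transcript length trend and of other splits of the libraries had their predictions written before their results were seen. The tests of a response to HgCl2, of RNA from another tissue, of variation between animals and of shared reads were chosen only after the pattern had been seen.

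The 7 transcripts called for the low dose at 34 h were more than most other splits of the 10 libraries gave: 2 of 100 splits had as many, the real one included, and the highest other had 10. Taken alone, this share excludes chance for the number of calls, but adjusted over the 11 comparisons it is 11%, which does not. A candidate explanation is a difference between animals of this outbred stock that was unevenly distributed over the groups. In the 15 libraries of 10 h, which played no part in the calls, the mean size of the pairwise correlation of the 7 within groups was 0.53, and 0.18% of 10000 random sets of like expression had as large a value (median 0.28). The random sets were matched on mean level only. The median SD within groups was 0.63 log2 units in the 7 and 0.22 in these sets. The 0.18% therefore does not compare sets of like spread and is a rough guide only. The mean of 0.53 rests on a block of 5 of the 7 with correlations of at least 0.77 in size, and the other 2 had correlations of at most 0.39 in size with any of the 7. Targets that share reads could vary together in this way too. Reads shared between targets remain open as well, since 0% of the 7 had whole counts, against 39.1% of the transcripts tested, and an effect of the low dose at 34 h was not excluded. Nor was a batch of the low dose libraries, which are 1 unbroken run of numbers (46 to 50).

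High dose replicate 2 at 10 h stood far from its group, at 0.564 log2 units where the other 4 libraries were at 0.265 to 0.322. Depth is argued against, since 164 transcripts stayed over 2-fold beyond all other libraries after every library was thinned to 20.2 M counts, and so is a trend with transcript length, since 172 stayed after centring within 20 length classes. The mean fragment length of this library, estimated from the effective lengths, was the longest of all libraries. It was 250.6 bp, where the other 4 were at 222.1 to 224.5 bp. Whether this bears on its distance was not tested. A response of this animal to HgCl2 that the other 4 lacked at 10 h may be a cause. The 46 transcripts it had over 4-fold above every 10 h vehicle were at 4.49 ± 0.47 log2(CPM + 1) (SD, n = 10) in the HgCl2 libraries of 34 h and at 4.15 ± 0.17 (n = 5) in the vehicle, an exact permutation p of 0.121, which leaves the question open. For the low dose of 34 h alone the mean was 4.33 ± 0.23 (n = 5, exact permutation p = 0.1825). For the high dose of 34 h alone the mean was 4.66 ± 0.62 (n = 5, exact permutation p = 0.0317, adjusted 0.0952 over 3 tests), and without its replicate 3, which stood at 5.75, the mean was 4.38 (exact p = 0.0556).

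Vehicle replicate 2 at 10 h, which received no mercury, stood 0.432 log2 units from its group, where the others were at 0.267 to 0.30. Thinning to equal depth left 291 transcripts beyond all other libraries, so depth is argued against. RNA of another tissue caught with the kidney is a candidate explanation, as most of the same 295 transcripts were in excess in 2 kidneys of other groups too. The median share of the excess was 13.0% (quartiles 10.7 to 15.1) in low dose replicate 4 and 16.9% (quartiles 11.2 to 21.7) in high dose replicate 5 at 34 h. The 295 were chosen as over 2-fold above all other libraries, which keeps large shares out. Across transcripts, the log2 excess in these libraries correlated with that in the vehicle library at 0.86 and 0.82, and the median share was at most 1.5% and r at most 0.65 in the other 27. Each r uses only the transcripts with an excess, 279 and 289 in these 2 libraries and 62 to 224 in the other 27. The values of r are therefore not over like sets. The tissue cannot be named without gene names, and no biological explanation was tested, since the design gives this animal no treatment.

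Other libraries had a value far from the other 4 of their group, which chance gives in about 1 of 20 groups (8 of 54 groups had one, these 2 libraries included). Genomic intervals held 9.23% of the counts of high dose replicate 4 at 34 h (others 6.35 to 6.95%) and 8.86% of vehicle replicate 4 at 10 h (others 6.34 to 6.81%). The 10 most abundant transcripts held 17.8% of the transcript counts of high dose replicate 2 at 34 h (others 15 to 15.7%). For ENSRNOT00000001792, low dose replicate 1 at 10 h stood at 26.3 CPM (others 19.7 to 21.5) and vehicle replicate 2 at 10 h at 17.1 CPM (others 20.2 to 21). For ENSRNOT00000072819, vehicle replicate 3 at 10 h stood at 8.65 CPM (others 5.15 to 5.84).

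The change of the high dose's effect between 10 and 34 h passed the test in 2 transcripts, with log2 differences of 5.56 and 1.00 (edgeR adjusted p = 0.0373 for both). Of 100 permutations of the doses within each time, 1, the real one, gave 2 or more calls, and the highest other gave 1. The 2833 transcripts at an unadjusted p under 0.05 were also reached by the real arrangement alone (1 of 100, highest other 2090). Taken alone, both shares exclude chance at a limit of 0.05, but adjusted over the 11 comparisons they are 11% and 9.17%, which do not. With 100 arrangements drawn, no share can be under 1 of 100. For a single comparison at that floor, the adjustment over 11 comparisons gives 11%. The adjusted shares are thus limited by the number of draws and do not decide whether chance gave these numbers. In 13 of 20 fits with 1 library left out there were 0 calls, and at 10 h dose and library number cannot be told apart.

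Among genomic intervals, which the report's comparisons leave out, edgeR called 2 for the low dose and 1 for the high dose at 10 h, and 1 for the low dose and 1 for the high dose at 34 h, of 14125 tested. The clearest was chromosome 14 at 46567362 to 46580400 (Rnor_6.0) in the high dose at 10 h, with 34.9 ± 6.15 CPM (SD, n = 5) against 15.5 ± 1.28 in the vehicle (log2 1.17, SE 0.13, edgeR adjusted p = 0.000383). The same interval stood at 18.46 ± 4.54 CPM in the low dose at 10 h. At 34 h its mean was lower in the high dose (18.57 ± 10.71 CPM) than in the vehicle (22.03 ± 4.49 CPM). In the low dose at 10 h, chromosome 4 at 81241784 to 81243969 (log2 0.71) and chromosome 5 at 147011775 to 147031774 (log2 1.26) were higher than in the vehicle, but there were 0 calls with the intervals' own library sizes and in 7 of the 10 fits that left out 1 library, and at 10 h dose and library number cannot be told apart. In the low dose at 34 h, chromosome 7 at 107870769 to 107890768 was higher (log2 0.76). In the high dose at 34 h, chromosome 4 at 96517799 to 96537798 stood at 0.59 ± 0.24 CPM against 0.02 ± 0.03 in the vehicle, where the 5 libraries held 3 counts in all. With 1 library left out, 0 intervals were called in 4 of 10 fits for the low dose and in 6 of 10 for the high dose at 34 h. Other splits gave as many calls in 5 of 100 (low dose 10 h, highest other 4), 15 (high dose 10 h, highest other 2), 23 (low dose 34 h, highest other 4) and 7 (high dose 34 h, highest other 3), so that chance is not excluded for these numbers.

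For the numbers of calls in the other comparisons, other splits show the following. The 1 call of the high dose at 10 h was matched by 10 of 100 splits (highest other 3) and that of the vehicle groups by 16 (highest other 3). A count of 0 is matched by all 100 splits. The highest other count was 19 for the low dose at 10 h, 2 for the high dose at 34 h, 58 and 1 for high against low dose at 10 and 34 h, 3 for the change of the low dose's effect, and 1 and 363 for the high and low dose over both times. Which splits gave the 58 and 363 was not examined, and a split can keep most libraries in their real group. Leaving out low dose replicate 4 of 10 h raised the real counts of these comparisons to 202 and 2075. The cause of the 58 and 363 was not tested.

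For the numbers of transcripts at an unadjusted p under 0.05, the share of splits, taken alone, excludes chance at a limit of 0.05 for the low dose at 34 h (3017, 3 of 100 splits, highest other 3811), for high against low dose at 10 h (3633, 4 of 100, highest other 4705) and for the low dose over both times (3886, 2 of 100, highest other 4701). Adjusted over the 11 comparisons each of these shares is 9.17%, so that chance is not excluded over all of them. Nor is it, even taken alone, for the low dose at 10 h (1904, 12 of 100, highest other 4616), the high dose at 10 h (2968, 5, highest other 3897), the high dose at 34 h (1165, 22, highest other 2498) and high against low dose at 34 h (678, 71, highest other 1771). The same holds for the change of the low dose's effect (1344, 21, highest other 4338), the vehicle groups (2039, 5, highest other 3651) and the high dose over both times (1453, 13, highest other 2936).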

How the results depend on the processing

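The alternatives with whole-count transcripts only, with the run of library numbers for the low dose at 34 h, with DESeq2 for the overlaps of calls, without the libraries that stand apart, of the profile tests and of the genomic intervals, and both comparisons over both times, were chosen after the data had been seen. The others were fixed before the data were examined. No paired analysis was possible because each animal gave 1 kidney library, and equal replicate numbers in different groups belong to different animals. The gene list tests and their alternatives, and the summing of counts per gene, were not run, since the files do not pair transcripts with genes. What follows gives counts of calls, and no cause of a shift was tested unless one is named.

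With DESeq2 in place of edgeR, the low dose gave 76 calls at 10 h and 443 at 34 h, the high dose 975 and 41, and high against low dose 1120 and 3. The change of effect gave 156 for the high and 19 for the low dose, the vehicle groups 131, and both times together 50 for the high and 884 for the low dose. With limma voom and quality weights, the high dose at 10 h gave 11, the low dose at 34 h 4, high against low dose at 10 h 2410, the change of the high dose's effect 4, the vehicle groups 0, and both times together 13 for the high and 1311 for the low dose. With all 30 libraries in 1 fit, the high dose at 10 h gave 62, the low dose at 34 h 0, high against low dose at 10 h 674, the change of the high dose's effect 1 and the vehicle groups 0. The size factors of DESeq2 in edgeR ended the call of the high dose at 10 h (0). Without a filter on low counts, the high dose gave 0 at 10 h and 1 at 34 h, and the change of its effect 0. With at least 5 CPM in 5 libraries, high against low dose at 10 h gave 2 and the change of the high dose's effect 1. On log2(TPM + 1), the high dose at 10 h gave 0 and high against low dose at 10 h 4.

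With whole-count transcripts only, which tests 8256, the low dose at 34 h gave 0, the high dose at 34 h 3, high against low dose at 10 h 30, the vehicle groups 0 and the high dose over both times 1. Without the libraries that stand apart, the high dose at 10 h gave 0, high against low dose at 10 h 184, the change of the high dose's effect 1, the vehicle groups 0 and the high dose over both times 5. Offsets for the effective length moved no count by over 1.5 times, and the run of library numbers as a covariate left both 34 h counts of the high dose at 0. Against the low dose, only the high dose libraries numbered 41 and 42 then set the difference, so that 0 says little on stability. For the low dose at 34 h that covariate gave 1 call, with log2 fold changes of 1.57 for ENSRNOT00000051422 (1.61 without it) and -0.70 for ENSRNOT00000051259 (-0.70). By construction, only the 3 vehicle libraries numbered 43 to 45 then set the difference. The overlaps of edgeR's calls were fixed at 0, since 1 side of each had 0 calls, so that their 0 with a 2-fold limit and with the vehicle libraries divided says nothing on stability. With DESeq2, 22 calls were shared between the doses over both times and 3 between 10 and 34 h of the high dose.

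With each library left out in turn, counts were 0 to 3 for the low dose at 10 h, 0 to 1 for the high dose at 10 h, 1 to 4 for the low dose at 34 h, 0 to 1 for the high dose at 34 h, 0 to 202 for high against low dose at 10 h, 0 to 5 and 0 to 2 for the change of the high and low dose's effect, 0 to 2 for the vehicle groups, and 0 to 4 and 0 to 2075 for the high and low dose over both times. High against low dose at 34 h stayed at 0.

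For genomic intervals, DESeq2 gave 14 and 42 for the low and high dose at 10 h and 13 and 2 at 34 h. The intervals' own library sizes gave 0 for the low dose at 10 h and 5 at 34 h. Without the libraries that stand apart there were 4 for the low and 8 for the high dose at 10 h. Leaving out single libraries gave 0 to 12, 1 to 9, 0 to 6 and 0 to 2, in the same order of groups.

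Of whole profiles, the exact permutation p of the variance between high dose and vehicle at 10 h was 0.111 with transcripts of at least 1 CPM and 0.0571 without the libraries that stand apart, and that of high against low dose at 10 h became 0.0238 without them. With single libraries left out, p was 0.0317 to 0.135 for the high and 0.0238 to 0.413 for the low dose at 10 h, 0.0238 to 0.167 for high against low dose at 10 h, 0.0238 to 0.103 for the low and 0.0476 to 0.857 for the high dose at 34 h. For the spread within groups, the difference turned in sign for the low dose at 10 h (exact p = 0.968 with whole counts, 0.865 without the libraries that stand apart), for the high dose at 10 h (0.825 with at least 1 CPM, 0.20 without those libraries) and for high against low dose at 10 h (0.429 without them). None of these passed the test on either side. At 34 h, without those libraries, high dose against vehicle gave 0.107 and high against low dose 0.0357. With single libraries left out, the exact p of the spread was 0.23 to 0.905 and 0.0873 to 1.0 for the low and high dose at 10 h, 0.238 to 0.913 for high against low dose at 10 h, 0.143 to 0.937 and 0.0079 to 0.0952 for the low and high dose at 34 h, and 0.0079 to 0.0794 for high against low dose at 34 h. In such fits the difference in spread also turned in sign: in 3 for the low dose, 2 for the high dose and 1 for high against low dose at 10 h. It turned in 1 for the low dose at 34 h as well (exact p = 0.833). The numbers of departing transcripts turned in sign at 10 h for high against low dose without the libraries that stand apart (exact p = 0.341), for high dose against vehicle at a 4-fold margin (0.841), and for low dose against vehicle at a 4-fold margin (0.381) and with at least 1 CPM (0.762). For high dose against vehicle at 34 h the exact p was 0.0714, and it was 0.0159 at a 4-fold margin, 0.0317 with whole counts, 0.103 with at least 1 CPM and 0.411 without the libraries that stand apart. With single libraries left out, the exact p of these departures was 0.198 to 0.944 and 0.27 to 0.857 for the low and high dose at 10 h, 0.341 to 0.937 for high against low dose at 10 h, 0.373 to 0.802 and 0.0238 to 0.23 for the low and high dose at 34 h, and 0.0556 to 0.325 for high against low dose at 34 h. The sign turned in 1 of these fits for each comparison at 10 h and in 1 for the low dose at 34 h (exact p = 0.754).

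The log2 fold changes of the named transcripts kept their sign in every setting run and with each library left out: 0.61 to 0.71 for ENSRNOT00000001792 (high dose at 10 h), and, for the low dose at 34 h, 1.40 to 1.70 for ENSRNOT00000051422, -0.76 to -0.63 for ENSRNOT00000051259 and 0.92 to 1.80 for ENSRNOT00000072819. Between the vehicle groups the last was at -1.78 to -0.90. The values smallest in size (0.61, 1.40, -0.63, 0.92 and -0.90) are differences in log2(TPM + 1), not fold changes of counts. In each case every library of 1 group lay on 1 side of every library of the other. Leaving out 1 library could then hardly turn the sign, so that the kept sign says nothing on stability. The calls of these transcripts mostly did not hold: with each of 10 libraries left out in turn, that of ENSRNOT00000001792 ended in 10 fits, of ENSRNOT00000051422 in 8, of ENSRNOT00000051259 in 9, and of ENSRNOT00000072819 in 6 for the low dose at 34 h and in 8 between the vehicle groups. Depth limits transcripts of low counts.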

Other observations

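All tests in this part were chosen after the data had been seen. Levels in this part are without TMM, except those of the transcript with no counts in the vehicle libraries of 34 h.

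Of the transcripts that high dose replicate 2 at 10 h had over 2-fold above all other libraries, the most abundant reached 5076.5 CPM. It stood at 451.8 CPM in high dose replicate 3 at 34 h and at 298.2 CPM in low dose replicate 3 at 10 h. The 46 transcripts that high dose replicate 2 had over 4-fold above all vehicles of its time stood, on average, at 4.91 ± 0.84 log2(CPM + 1) (SD, n = 5) in the low dose and at 4.09 ± 0.11 in the vehicle at 10 h (exact permutation p = 0.135). The single low dose libraries were at 5.26, 5.35, 5.89, 3.99 and 4.07. The vehicle libraries of 10 h helped choose the set, so that this p favours a difference.

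High dose replicate 4 at 34 h had low levels of many targets that the other libraries had. Of the genomic intervals of at least 1 CPM in all 29 other libraries, 12% were lower there by over 2-fold than in any of them, and 3.42% of such transcripts were. Those intervals stood at 25.6% and those transcripts at 27% of their median elsewhere. At the same time its share of counts on intervals was the highest of all libraries, and 3 intervals led its excess: chromosome 14 at 46634208 to 46645665 (14650.9 CPM), chromosome 1 at 11907094 to 11915036 (14209.4 CPM) and chromosome 14 at 46646819 to 46649470 (11958.8 CPM), all in Rnor_6.0. The same 3 intervals led the excess of vehicle replicate 4 at 10 h, at 6791.3, 7581.6 and 9363.8 CPM. The medians elsewhere were 861.5, 740.5 and 1239.2 CPM. The interval that was higher in the high dose at 10 h lies on chromosome 14 as well, at 46567362 to 46580400.

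One transcript called for the low dose at 34 h had no counts in any of the 5 vehicle libraries of that time. It also had none in 1 or 2 libraries of each of 4 other groups, at both doses and in the vehicle of 10 h, and up to 5.65 CPM in others of the same groups. Within groups at 10 h its correlation with the other 6 called transcripts was -0.17 to 0.26, so that it lies outside the block of 5 that varied together. It did not have whole counts, and reads shared with other targets were not excluded.

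Within groups at 10 h, the 7 transcripts called for the low dose at 34 h had a median SD of 0.63 log2 units, where random sets of like expression had 0.22, and 0.01% of 10000 sets had as large a value. The next correlations are within groups, over all 30 libraries with the mean of each group taken off. Of 17242 transcripts of at least 1 CPM, 5 correlated with the block at 0.7 or more in size, and these are the block's own members. Of 12104 genomic intervals, chromosome 1 at 88285761 to 88305760 (Rnor_6.0) was at -0.77 and the next at 0.65. Of the next 9 intervals, 2 lay within 1 Mb of it, at 0.64 and -0.64. This was noticed before it was tested (one-sided exact hypergeometric p = 0.00026), so that the p decides nothing.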
